A study of Mus musculus with 12 samples.

How the data were processed

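RNA was sequenced from T-positive cells isolated by flow cytometry from mouse embryos and from Day 4 in vitro differentiation cultures on a mixed 129S2 and C57BL/6J background. Per the labels' protocols, cells were sorted straight into lysis buffer and libraries were made with a ScriptSeq v2 Complete low-input kit. The deposited table holds 1 FPKM column (fragments per kilobase of gene model scaled by the number of mapped fragments) for each of 5 libraries. Per the submitters' processing notes, the tools named for the series are TopHat2 2.0.8, Cufflinks 2.1.1 and bedtools 2.23.0, with genome build mm10; the notes used here give neither roles nor order. The FPKM were used as deposited by the authors. Whether the authors counted reads by strand is not given in the sources used here, so overlapping antisense transcripts, such as those over Rtl1, cannot be separated. The 7 chromatin immunoprecipitation samples were not analysed here.

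Columns were matched to samples by the numbers and stages in the labels; 5 columns were matched and 0 were left unused. The column matched to the embryo library labelled wild type shares its first letters with the T_Y88A columns, so directions rest on the label. The labels give no replicate numbers, and nothing says that libraries came from separate animals or cultures. Of 23421 symbols, 22045 matched a current symbol in the RefSeq gene table of GRCm38.p6 (mm10) or a table of gene names and 23288 did so with synonyms; 14 symbols had been turned into dates. Coordinates are those of that RefSeq table, counted from 1. Small RNA genes (774 symbols, 70 of them above the filter in embryos) were left out, since short transcripts have unstable FPKM; some kept their place under accession-like symbols. 3 list genes (in no row of the table) had no value. An exact 0 can be a failed estimate: 3 genes (G3bp2, Cnot1 and Nolc1) were at 0 in 1 library and above 20 FPKM in the other 4. Such genes are described as listed at 0. Their log2 differences rest on the added 1 and measure no fold.

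Relative depth was estimated from values below 0.06 FPKM, where 1 fragment sets the step between values: the commonest ratio between 2 libraries over 112 to 193 low genes, within 0.03 on the log2 scale, held 16.5% to 25.9% of them. Absolute depth, and so counting intervals and detection limits, cannot be had from FPKM.

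Values were analysed as log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the libraries compared. A fold on this scale understates the change of low genes. R 4.3.3 and limma 3.58.1 were used, with Python 3.11.15 and matplotlib 3.10.9 for the plots. For the embryos, limma with a variance trend compared 2 T_Y88A libraries with 1 labelled wild type, which was assumed to vary like the T_Y88A libraries. The residual degrees of freedom were 1 and the prior degrees of freedom 10.6. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Tested on 20 simulated sets of the embryo comparison with 200 of 11152 genes changed, this fit recovered 40.0% of 2-fold and 94.1% of 4-fold changes with a mean of 24.9 false calls, 14.9% of all calls; the rule of size found 99.4% of the 4-fold changes. That rule counted genes at least 2-fold apart in the same direction in both T_Y88A libraries. Its chance level came from 100 simulated sets of unchanged libraries with the spread of the T_Y88A libraries. Stage and Day 4 comparisons had 1 library each and no test. A fit over all 5 libraries had the system (embryo or Day 4) as a covariate and 2 residual degrees of freedom; a further fit added the interaction of system and genotype, chosen after seeing the data. Median log2 shifts over all genes lay between -0.03 and 0.00.

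30 gene lists were fixed before the data were examined. They cover streak and caudal epiblast, presomitic mesoderm, somite, notochord and node, neural, surface ectoderm, endoderm, lateral plate and cardiac mesoderm, blood and endothelium, pluripotency and germ cell, mesenchyme, and visceral and extraembryonic genes, WNT, FGF, NOTCH, BMP and TGF-beta, retinoic acid, p53 and hypoxia genes, 3 groups of Hox paralogs, histone acetyltransferases and deacetylases, Polycomb and trithorax, cell cycle, immediate early, sex-linked, ribosomal protein, mitochondrial and histone genes. The 27 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. At the preset correlation 10 lists passed; with an estimated correlation 0 passed (1 at an unadjusted p under 0.05) and with fry 0 (2 at an unadjusted p under 0.05). A correlation estimated from 1 residual degree of freedom is itself imprecise. Medians of single libraries were set against 10000 random lists of the same size matched on mean expression, as a description of these libraries.

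Named genes follow a rule fixed before the data were examined: T first; the 10 largest increases and decreases per comparison by the smaller of the 2 T_Y88A ratios, with at least 5 FPKM in the higher group and without unnamed, predicted or small RNA genes; up to 4 members per list; and a panel of 18 developmental genes. Other genes named in the text (Sox1, Pax3, Irx3, Pou5f1, Hist1h2bq, Hba-a2, Bmp2, Bmp4, Fabp7, Hes5, Olig3, the listed members of gene lists and the genes that a count of 10 or fewer holds) were chosen after their values were seen. Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, quantile normalization, scaling by the median of ratios, small RNA genes kept, other variance settings, all groups in 1 fit, 1.5-fold and 4-fold limits, and leaving out libraries. Leaving out genes listed at 0 was added after seeing the data.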

Results

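Expression was measured by RNA sequencing in cells sorted by flow cytometry for T (Brachyury), the T-box transcription factor of the primitive streak and the forming mesoderm. The sorted cells came from mouse embryos at Theiler stages TS12 and TS13, the stages of early somite formation, and from cultures at Day 4 of mesodermal differentiation from embryonic stem cells. The mutant genotype, T_Y88A, carries an amino acid substitution in T. The embryo set held 1 library labelled wild type, from TS12 and TS13 together, and 2 T_Y88A libraries, 1 of each stage. The Day 4 set held 1 library labelled wild type and 1 T_Y88A library. All values were FPKM of 23421 gene symbols. A further 7 chromatin samples of the series were not analysed here. FPKM keep no read totals, so the absolute depth is unknown. From the steps between low values, the depth relative to the embryo library labelled wild type was 0.763 for T_Y88A TS12, 0.986 for T_Y88A TS13, 1.05 for the Day 4 library labelled wild type and 0.490 for Day 4 T_Y88A. Across genes, the log2 values of the 2 T_Y88A embryo libraries correlated with r = 0.988, and each correlated with the library labelled wild type at 0.974 and 0.975.

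T itself (chromosome 17, 8434423 to 8442496, mm10) was present in all 5 libraries, as the sort requires. It stood at 65.9 FPKM in the embryo library labelled wild type, 69.8 in T_Y88A TS12 and 26.99 in T_Y88A TS13, and at 72.9 and 32.5 in the Day 4 libraries labelled wild type and T_Y88A. A substitution need not change the RNA level, so these values do not check the genotypes. The deposited column of the embryo library labelled wild type has a name that begins like those of the T_Y88A columns. The series description also speaks of heterozygous embryos as wild type. Every direction given for the embryos below therefore rests on the sample label.

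The embryo comparison asks which genes differ in T-positive cells of T_Y88A embryos. Most measured genes of the presomitic mesoderm, the tissue that segments into somites, were lower in both T_Y88A libraries than in the library labelled wild type. Msgn1 (chromosome 12, 11208382 to 11208948), a master regulator of presomitic differentiation, fell from 41.1 FPKM to 3.10 ± 0.550 (SD, n = 2), a log2 difference of -3.37 ± 0.22 (SE). Dll1, the NOTCH ligand of the presomitic mesoderm (chromosome 17, 15367354 to 15376932), fell from 44.3 to 9.28 ± 2.11 FPKM (SD, n = 2). Rspo3, a secreted amplifier of WNT signalling (chromosome 10, 29453106 to 29535867), fell from 56.2 to 10.8 ± 3.83 FPKM (SD, n = 2). Tbx6 (chromosome 7, 126781483 to 126785548), which directs cells to paraxial mesoderm, stood at 12.6 FPKM against 4.79 and 1.60 in the TS12 and TS13 T_Y88A libraries.

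Of the 15 presomitic genes measured, 9 fell, 1 rose and 5 did not pass limma's test, and 10 fell and 1 rose when adjusted over the list alone. The median log2 difference of the list was -1.30 (camera adjusted p = 1.31e-12; adjusted p = 0.853 with an estimated correlation). The riser was Hes3, a hairy-related repressor also known from neural progenitors, at 1.62 FPKM in the library labelled wild type and 8.77 ± 2.52 in T_Y88A (SD, n = 2). Among 7 somite genes, Meox1, Tcf15 and Foxc1 fell and 4 did not pass, with 3 lower and 1 higher when adjusted over the list alone. The list median was -0.62 (camera adjusted p = 0.00484; adjusted p = 0.853 with an estimated correlation; 0.109 with no filter). Of 13 NOTCH and segmentation clock genes, Dll1, Lfng and Nrarp fell. All 3 are also in the presomitic list, so this is no separate result. NOTCH genes outside the presomitic list, such as Hey1 (log2 difference -0.64) and Hes1 (0.02), did not pass over all genes. Of the NOTCH and segmentation clock list, 5 fell when adjusted over the list alone, Hey1 among them. That list had a median of -0.53 (camera adjusted p = 3.45e-06; adjusted p = 0.853 with an estimated correlation). The call for Tbx6 (adjusted p = 0.0273) ended at a pseudocount of 0.1 (0.0515), under quantile normalization (0.167), with small RNA genes kept (0.0564), without the variance trend (0.0806) and with robust variance estimates (0.243).

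**Figure D1:**
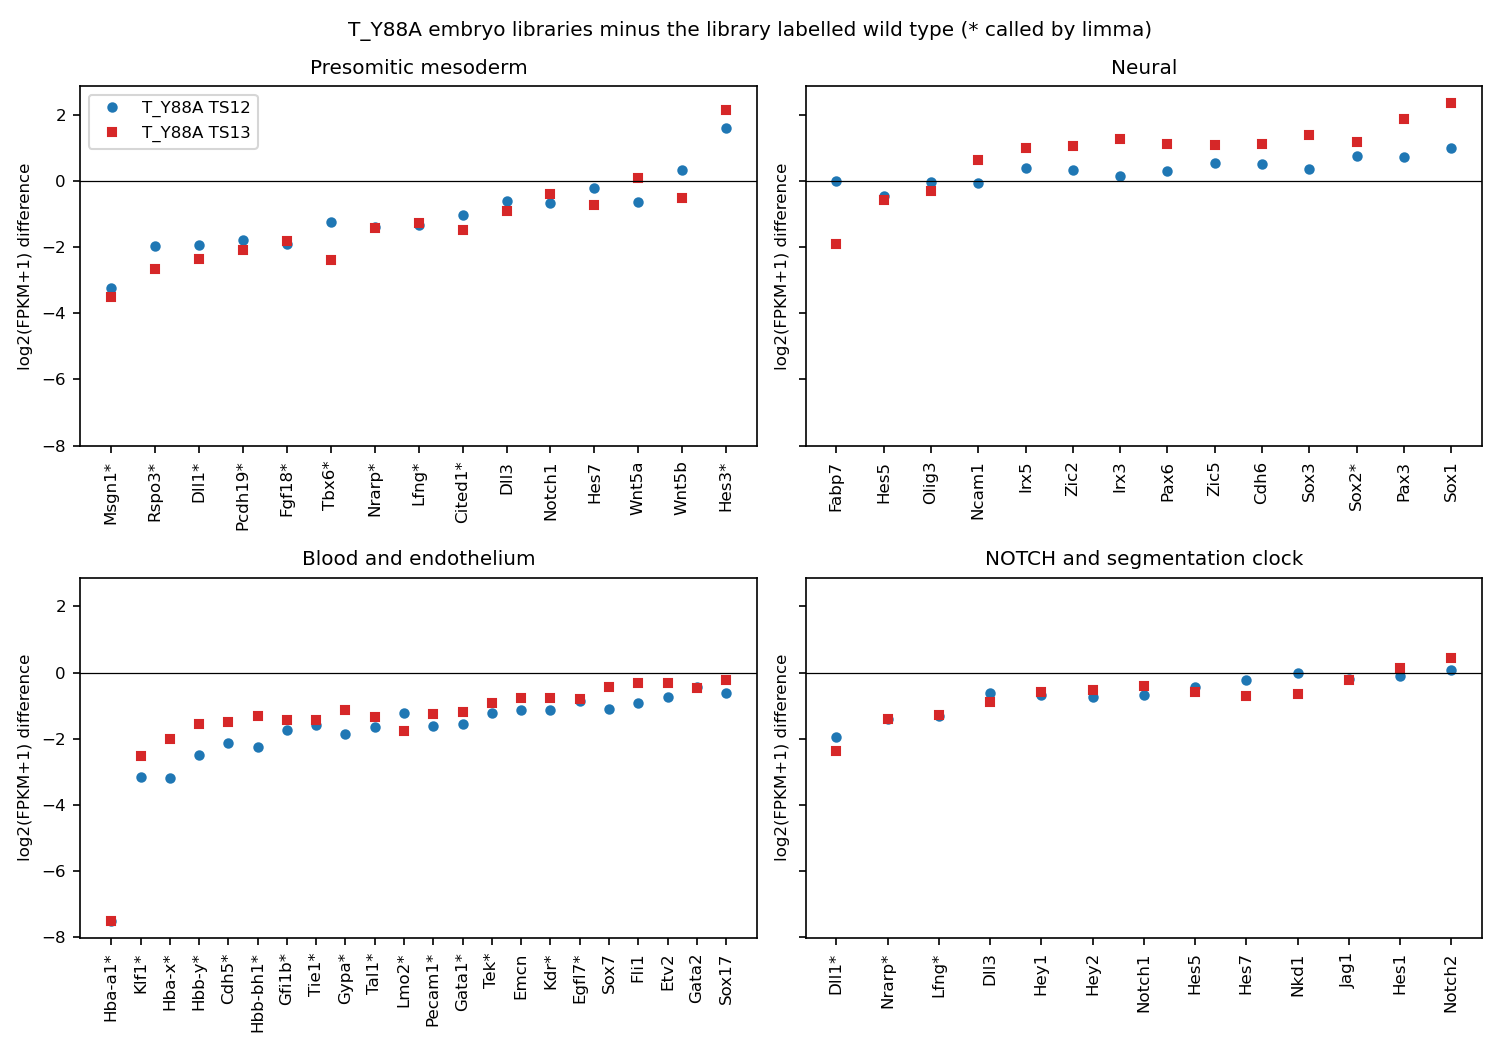
Differences in log2(FPKM + 1) between each T_Y88A embryo library (circles, TS12; squares, TS13) and the 1 library labelled wild type, for the measured genes of 4 lists; asterisks mark genes with a limma adjusted p under 0.05. The presomitic genes from Msgn1 to Cited1 and all 22 blood and endothelial genes lie below 0 in both T_Y88A libraries.

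Blood and endothelial genes were lower in both T_Y88A embryo libraries. Of 22 measured, 16 fell and 6 did not pass, and 19 fell when adjusted over the list alone. Embryonic globin Hba-x stood at 1625 FPKM in the library labelled wild type, 177 in T_Y88A TS12 and 399 in T_Y88A TS13. Klf1, the erythroid transcription factor that activates globin genes, had a log2 difference of -2.85 ± 0.30 (SE), and the endothelial cadherin Cdh5 one of -1.81 ± 0.29 (SE). The list median was -1.46 (camera adjusted p = 7.73e-25; adjusted p = 0.853 with an estimated correlation). Hba-a1 fell from 184 FPKM to 0.0115 and 0.0232, but its near-identical copy Hba-a2 held 1880, 279 and 612 FPKM, so the split of reads between the 2 genes is uncertain.

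The neural list stood higher by its median in the T_Y88A embryo libraries, more so at TS13. Sox2, a transcription factor of neural progenitors, rose from 17.9 to 36.1 ± 7.54 FPKM (SD, n = 2; log2 difference 0.95 ± 0.20 SE, adjusted p = 0.0340). It was the 1 member of 14 to pass over all genes, and 5 rose when adjusted over the list alone. The list median was 0.71 (camera adjusted p = 0.000252; adjusted p = 0.853 with an estimated correlation; 0.109 with no filter), made up of 0.34 in T_Y88A TS12 and 1.10 in T_Y88A TS13. Sox1 went from 0.232 FPKM in the library labelled wild type to 1.47 and 5.37, and Pax3 from 2.25 to 4.40 and 10.8, without passing (adjusted p = 0.0755 and 0.0978). Fabp7 (2.84, then 2.84 and 0.0325), Hes5 and Olig3 had log2 differences of -0.95, -0.52 and -0.17, and did not pass either. The Sox2 call ended under quantile normalization (0.137), with small RNA genes kept (0.0564) and without the variance trend (0.101).

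Caudal epiblast genes did not move together. Nkx1-2, a marker of the progenitors shared by spinal cord and paraxial mesoderm, rose from 33.2 to 75.3 ± 23.5 FPKM (SD, n = 2), while Cyp26a1, which degrades retinoic acid at the tail end of the embryo, fell from 28.8 to 4.23 ± 0.211 FPKM (SD, n = 2). The other 14 of the 16 streak and caudal epiblast genes did not pass, and the counts were the same when adjusted over the list alone. The list median was 0.05 and its mean -0.05 (camera adjusted p = 0.716). Cdx2 stood at 73.8 FPKM in the library labelled wild type and at 86.8 ± 20.5 (SD, n = 2) in T_Y88A. Wnt3a (12.1 FPKM in the library labelled wild type, then 13.6 and 2.02) and Evx1 (7.63, then 9.86 and 5.71) lay on both sides of the library labelled wild type in the 2 T_Y88A libraries. Fgf8, a growth factor of the streak, stood at 13.1, 9.99 and 3.78 FPKM (adjusted p = 0.222).

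Notochord genes were measured at low levels in the embryos. Shh, the signal secreted by the notochord, fell from 4.06 FPKM to 0.0478 and 0.390 (log2 difference -2.07 ± 0.31 SE). Noto, the homeobox gene of the node and notochord, stood at 2.97 FPKM in the library labelled wild type and was listed at 0 in both T_Y88A libraries. Foxa2 stood at 1.85, 0.704 and 0.128 FPKM, and Mixl1 at 2.67, 0.167 and 0.0973 FPKM, below the level tested. Of 5 notochord and node genes tested, 1 fell, and 1 rose and 1 fell when adjusted over the list alone (median -0.17, camera adjusted p = 0.487). Of 9 endoderm genes, Nepn fell, and 5 fell when adjusted over the list alone (median -0.78, camera adjusted p = 0.00320; adjusted p = 0.853 with an estimated correlation; 0.190 with no filter). Eomes and Mesp2 stood under 0.2 FPKM in the 3 embryo libraries. Mesp1 had 1.32, 1.01 and 0.529 FPKM and Snai1 0.576, 0.583 and 0.219 FPKM, in the order labelled wild type, TS12 and TS13.

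Among signalling lists, BMP and TGF-beta targets had a median log2 difference of 0.31 (camera adjusted p = 0.0393; adjusted p = 0.853 with an estimated correlation). Id2, a BMP-induced inhibitor of helix-loop-helix factors, was the 1 of 14 to rise, and 3 rose when adjusted over the list alone. This call ended under quantile normalization (adjusted p = 0.0666), and with no filter on low values camera gave the opposite direction (adjusted p = 0.972). WNT targets had 1 of 15 genes lower (Dkk1; median -0.28, camera adjusted p = 0.0510). FGF targets had 1 of 18 lower (Fgf18; median -0.03, adjusted p = 0.512). The retinoic acid list had 1 of 9 lower (Cyp26a1; median 0.24, mean -0.07, adjusted p = 0.564). Adjusted over the list alone, the counts were 1 lower for WNT, 1 lower for FGF, and 1 lower and 1 higher for retinoic acid. Hypoxia and glycolysis genes had a median of 0.18 with 0 of 17 passing over all genes or when adjusted over the list alone (camera adjusted p = 0.0200; adjusted p = 0.853 with an estimated correlation). That call ended with no filter (0.0727) and under quantile normalization (0.0537).

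The remaining lists did not pass. Lateral plate and cardiac mesoderm had Tbx4 and Osr1 lower among 16 (adjusted p = 0.333). Pluripotency and germ cell genes had Sox2 higher and Dppa3 lower among 9 (0.244). Mesenchyme genes had Fn1 lower among 15 (0.244), p53 targets Pmaip1 higher and Plk2 lower among 15 (0.105), and visceral and extraembryonic genes Rhox5 lower among 8 (0.0510). Hoxb9 rose among the 15 Hox genes of paralog groups 5 to 9 (median -0.11, mean -0.01, camera direction up, 0.878). No gene passed among 12 Hox genes of groups 1 to 4 (0.716), 15 surface ectoderm (0.935), 10 immediate early (0.539), 20 cell cycle (0.775), 17 Polycomb and trithorax (0.999) or 19 histone acetyltransferase and deacetylase genes (0.935). Adjusted over the list alone, these 12 lists gave 2 lower in lateral plate, 1 higher and 2 lower in pluripotency, 1 higher and 1 lower in mesenchyme, 3 higher and 1 lower in p53 targets, 4 lower in visceral, 1 higher and 1 lower in Hox 5 to 9, 1 higher and 2 lower in surface ectoderm, 2 lower in immediate early genes and 0 in the other 4. The acetyltransferase and the Polycomb lists had medians of 0.02 and 0.03 and means of -0.03 and -0.01. Too few genes were measured to test Hox groups 10 to 13 (3 genes, 0 passing, 3 lower when adjusted over the list alone) and sex-linked genes (3 genes, with Uty higher, and 2 higher when adjusted over the list alone), and 0 mitochondrial messenger RNA genes were in the table.

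Histone genes were higher by their median in the T_Y88A embryo libraries. The list joins replication-dependent genes, whose messenger RNAs mostly lack a poly(A) tail, with variants made outside replication, such as the linker histone H1fx (1.58 FPKM, then 3.78 and 4.99; adjusted p = 0.0614). Of 74 measured, 18 rose and 0 fell, and 39 rose when adjusted over the list alone (median 0.48, camera adjusted p = 1.09e-22; adjusted p = 0.853 with an estimated correlation). Hist1h2bq, for example, stood at 19.3 FPKM against 43.4 and 36.4. Ribosomal protein genes had Rps27 and Rpl30 higher among 79, and 3 higher when adjusted over the list alone (median 0.20, camera adjusted p = 2.94e-07; adjusted p = 0.853 with an estimated correlation). Many histone genes are near copies of one another, and Rps27 has near-identical copies, so single values in both lists are uncertain. The ribosomal RNA precursor Rn45s moved the other way, at 2537 FPKM in the library labelled wild type and 1308 and 1316 in T_Y88A.

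Outside these lists, H19, Rian and Arg1 had the largest decreases by the fixed rule. H19 (chromosome 7, 142575530 to 142578146), a maternally expressed noncoding RNA, fell from 1154 FPKM to 15.6 ± 0.984 (SD, n = 2), a log2 difference of -6.12 ± 0.16 (SE). Rian and Meg3, maternally expressed noncoding RNAs of the imprinted Dlk1-Dio3 domain on chromosome 12, fell from 55.0 to 0.777 ± 0.248 FPKM and from 7.58 to 0.0573 ± 0.00978 FPKM (SD, n = 2). Mirg and the small nucleolar RNA AF357355 of the same domain fell too, AF357355 being listed at 0 in both T_Y88A libraries. Arg1, the arginine-degrading enzyme, fell from 29.7 to 1.69 ± 0.474 FPKM (SD, n = 2). The largest increases by the fixed rule were Rps27, Amd1, Rmnd1, Hes3, Tlcd2, Nup62cl, Rabl5, Dpm3, Pigp and Pygo2. Amd1 (0.0110 FPKM, then 8.39 and 43.7) and Rmnd1 (0.000329 FPKM, then 9.70 and 7.15) were almost empty in the library labelled wild type, so these folds are uncertain. The calls for Rps27 and Amd1 ended with robust variance estimates (0.208 and 0.581). Under quantile normalization only Rps27 and Rmnd1 of these increases kept their calls, and the others had adjusted p from 0.0840 to 0.116.

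**Figure D2:**
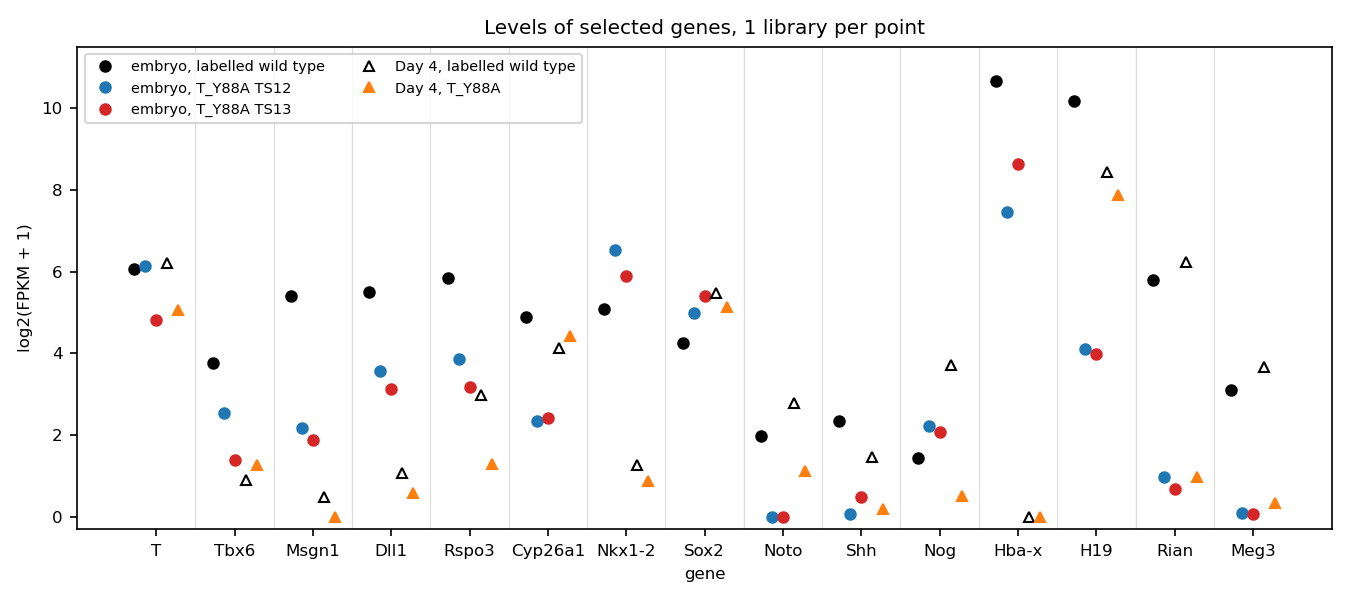
Expression of 15 genes as log2(FPKM + 1), 1 point per library; circles are embryo libraries and triangles Day 4 libraries. Rian stands at 55.0 and 74.0 FPKM in the libraries labelled wild type and at 0.968 or less in the 3 T_Y88A libraries, while H19 differs in the embryos (1154 against 16.3 and 14.9) more than at Day 4 (346 against 234).

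In all, limma called 256 of 11152 genes in the T_Y88A embryos, 82 higher and 174 lower (1825 genes had an unadjusted p under 0.05). By the rule of size, 201 genes differed at least 2-fold in the same direction in both T_Y88A libraries, 41 higher and 160 lower. Simulated unchanged libraries sharing the 1 control gave a mean of 12.6 higher (6 to 22) and 12.4 lower (4 to 22), and independent lists would share 1.41 and 5.68. With T_Y88A TS12 or T_Y88A TS13 in the place of the library labelled wild type, the counts were 31 and 42. Across genes, the 2 ratios correlated with r = 0.756 against 0.500 in the simulation, and their covariance was 0.152 against 0.0495; with 1 control library, part of the excess may come from that library. The spread in limma came from the difference between the 2 T_Y88A libraries (1 residual degree of freedom) and from variances shared across genes. It treats the stage difference as noise, and the 1 library labelled wild type adds nothing to it. Nothing states that the libraries came from separate litters, so these p-values measure no spread between animals. The count of 256 fell to 17 (3 higher, 14 lower) under quantile normalization, where the calls for Rspo3 (0.0592) and Shh (0.0840) ended too, and to 0 with no filter on low values, where limma gave 2258 of 17379 genes at an unadjusted p under 0.05.

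The 2 T_Y88A embryo libraries differ in stage, with 1 library each, and no test was run. By their medians, the neural list stood higher in TS13 than in TS12 and the streak and caudal epiblast list lower, with exceptions in each. Sox1 stood at 1.47 FPKM in T_Y88A TS12 and 5.37 in T_Y88A TS13, and Irx3 at 6.23 and 14.7. Pou5f1, the pluripotency factor that shuts down as the epiblast is exhausted, stood at 55.7 and 6.07, and Wnt3a at 13.6 and 2.02. Against their lists, neural Fabp7 (log2 difference -1.90), Olig3 (-0.28) and Hes5 (-0.14) stood lower in TS13, and Sp8 (0.11) and Cyp26a1 (0.08) of the streak list higher. The neural list had a median log2 difference of 0.65, above all 10000 random lists (percentile 100), and the streak list one of -0.67, at percentile 0. Endoderm (-0.67), WNT targets (-0.45), surface ectoderm (-0.35) and presomitic mesoderm (-0.28) lay at percentile 0 too, and immediate early genes (0.57), blood and endothelium (0.37), Hox groups 5 to 9 (0.33) and hypoxia and glycolysis (0.30) at percentile 100. By size, 114 genes differed at least 2-fold, 50 higher and 64 lower in TS13. That count moved to 286 with a pseudocount of 0.1 and to 27 with a pseudocount of 5.

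The Day 4 comparison asks what T_Y88A changes in sorted T-positive cells made in culture. The notochord and node list stood lower by its median in the T_Y88A library. Nog, a BMP antagonist made by the notochord, was at 12.1 FPKM in the library labelled wild type and 0.431 in T_Y88A, Noto at 5.87 and 1.19, and Shh at 1.77 and 0.146. The list's median log2 difference was -0.53 over 13 genes, 6 of them at least 2-fold lower, below all 10000 random lists. Shh lay below the level measured and is not among the 13. Foxa2 (28.7 and 19.6 FPKM), Foxj1 (27.4 and 21.4) and Chrd (5.52 and 4.87) were lower by less than 2-fold. The list's members Nodal (log2 difference 0.76), Lefty2 (0.73), Lefty1 (0.67) and Dand5 (0.47) stood higher. The Dlk1-Dio3 RNAs were again near 0 in T_Y88A, with Rian at 74.0 and 0.968 FPKM and Meg3 at 11.6 and 0.257.

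The streak and BMP lists stood higher by their medians in Day 4 T_Y88A cells, with single members in both directions. Id1, a direct BMP target, was at 2.70 FPKM in the library labelled wild type and 13.8 in T_Y88A, Fgf8 at 26.5 and 54.3, and Eomes, a T-box factor of the early streak, at 4.27 and 9.43. The BMP ligands Bmp2 and Bmp4 stood lower in T_Y88A (log2 differences -1.57 and -0.79), as did Nog and T, which belong to these lists too. At least 2-fold apart were 1 BMP and TGF-beta member higher and 2 lower, and 1 streak member higher and 1 lower. The list medians were 0.47 for BMP and TGF-beta targets (17 genes), 0.46 for the retinoic acid pathway (8 genes), 0.34 for streak and caudal epiblast genes (15 genes) and 0.25 for hypoxia and glycolysis genes (17 genes), each above percentile 99. Presomitic genes had no common direction at Day 4. Rspo3 stood at 6.94 FPKM in the library labelled wild type and 1.45 in T_Y88A, Nrarp at 4.67 and 8.14, Dll3 at 4.91 and 5.12 and Notch1 at 6.46 and 6.04. Msgn1 stood at 0.409 FPKM and was listed at 0 in T_Y88A, Tbx6 was at 0.879 and 1.39, and Dll1 at 1.12 and 0.498. The median of 8 presomitic genes was -0.07 (percentile 28.0). In total 227 of 11559 genes differed at least 2-fold, 74 higher and 153 lower, in 1 library against 1 with no replicate check. The T_Y88A library had 0.476 times the relative depth and more ribosomal RNA precursor (Rn45s at 1801 and 6061 FPKM), Lars2 stood at 644 and 4686 FPKM, and Nolc1 and Cnot1 were listed at 0 in the library labelled wild type.

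The rule for Day 4 also named Eif3j1 (34.8 FPKM in the library labelled wild type, 0.00487 in T_Y88A), Hist2h2aa2 (213 and 18.3), Akr1b3 (35.8 and 3.65) and the small nucleolar RNAs AF357425 (22.9 and 0.707) and DQ267102 (6.21, then listed at 0) as lower. Amd2 (0.00899 and 41.3), Tmem38b (7.16 and 89.7), Npy (1.49 and 9.67), Hist1h4j (13.9 and 47.7), Eif3j2 (6.84 and 24.0) and Espn (1.15 and 5.56) were named as higher. Eif3j1 and Eif3j2, Amd1 and Amd2, and the histone genes have near-identical copies, so their values are uncertain.

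With embryo and Day 4 libraries in 1 fit, the genes that differed by genotype in both systems were mostly those of the Dlk1-Dio3 domain. limma called 10 of 11611 genes, 2 higher and 8 lower (1123 at an unadjusted p under 0.05). Rian (log2 difference -5.10 ± 0.19 SE, adjusted p = 3.45e-05), AF357355, Meg3, Mirg, 6430411K18Rik and Rtl1 lie between Dlk1 and Dio3 (chromosome 12, 109452485 to 110281097). Rspo3 fell by 2.05 ± 0.25 (SE) and Noto by 1.84 ± 0.21 (SE), the 2 lower genes outside the domain. The unnamed transcripts Gm12238 and Gm20594 were higher. Gm12238 was listed at 0 in both libraries labelled wild type, so its difference measures no fold. Of 10420 genes measured in both systems, 9 were at least 2-fold lower in both (0.665 for independent lists): the 6 domain genes, Rspo3, Dppa3 and Limch1. The 6 domain genes are neighbours that partly overlap in position, so they do not count as separate events. Gm12238 and Gm20594 were higher in both (2 genes, 0.191 for independent lists). Opposite directions also exceeded independence, with Amd1 and Rps27 higher in the embryos and lower at Day 4 (2 genes, 0.302) and Gata1 and Lars2 the other way (2 genes, 0.421). Lars2 rose and fell with the ribosomal RNA precursor Rn45s. Across genes, the embryo and Day 4 differences hardly correlated (r = 0.0815, rho = 0.0522), and genes are not independent replicates. The count of 10 ranged from 4 to 24 when 1 library was left out (18 without the embryo library labelled wild type, 4 without T_Y88A TS13, 24 without the Day 4 library labelled wild type and 19 without Day 4 T_Y88A). It was 6 with a pseudocount of 0.1 and 1 with no filter or with a mean of at least 5 FPKM. Without the embryo library labelled wild type, the genotype effect of this fit is that of the Day 4 pair alone, and most of the 10 lost their calls. Without either Day 4 library, it is that of the embryos alone. None of these refits kept all 10 genes, and each checks 1 system only, not genes that differ in both.

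**Figure D3:**
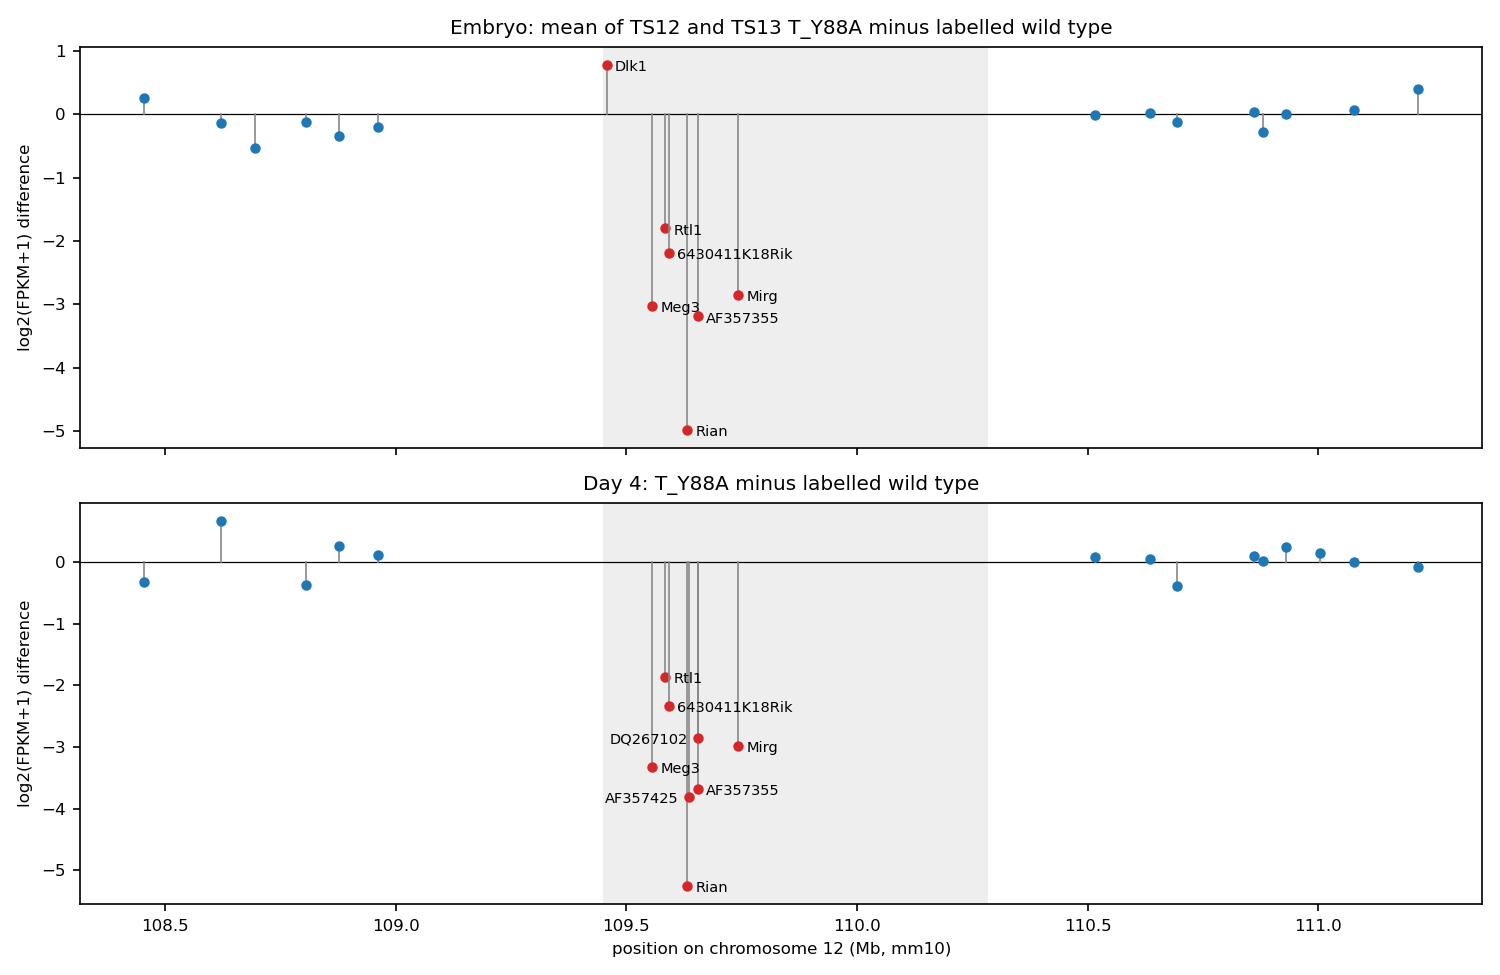
Differences in log2(FPKM + 1) between T_Y88A and the library labelled wild type along chromosome 12, for genes past the filter within 1 Mb of the Dlk1-Dio3 domain (grey). Red points are genes inside the domain and blue points genes outside; in the embryos 6 of 7 inside genes lie at or below -1, and at Day 4 all 8, while 0 of 14 outside genes do so in either set.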

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

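All tests in this part were chosen after the results were seen. 14 genes had a Day 4 effect of T_Y88A that differed from the embryo effect in limma's interaction term (1467 at an unadjusted p under 0.05), given here as the log2 Day 4 effect minus the embryo effect. The value was 5.56 for H19, 7.51 for Hba-a1 (at most 0.000813 FPKM at Day 4), 4.78 for Lars2 and -3.91 for Nog. Lars2 and the ribosomal RNA precursor Rn45s were both highest in Day 4 T_Y88A (4686 and 6061 FPKM). Both were lowest in the T_Y88A embryo libraries (Lars2 325 and 277, Rn45s 1308 and 1316). The Lars2 value therefore cannot be told apart from the ribosomal RNA content of the libraries. Nog stood higher in the T_Y88A embryo libraries (1.71, then 3.70 and 3.19 FPKM) and lower in Day 4 T_Y88A (12.1, then 0.431). The value was 5.91 for Nolc1 and 5.09 for Cnot1, both listed at 0 in the Day 4 library labelled wild type; these values rest on zeros that can be failed estimates and measure no change. It was -4.56 for Eif3j1, 5.00 for Amd2 and -6.18 for Rps27, which have near-identical copies. It was -3.23 for Akr1b3, -2.32 for Rps21, -3.37 for AF357425, -3.86 for Gm7334 and 2.27 for BC002163. AF357425 stood at only 0.348 FPKM in the embryo library labelled wild type and was listed at 0 in both T_Y88A embryo libraries. Its level in the embryos was too low to show a genotype effect, so its value shows no difference in effect. The 1 residual degree of freedom of this fit is the difference between the T_Y88A TS12 and TS13 embryo libraries. No spread was measured at Day 4, and the test took it to be like that of the embryos. With 1 library per group at Day 4, a single aberrant library gives such a difference too.

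The RNAs of the Dlk1-Dio3 domain were near 0 in all 3 T_Y88A libraries, and 2 technical explanations were tested. Lower recovery of long noncoding RNA would lower other such RNAs, but their median log2 difference was 0.0937 over 237 in the embryos and 0.11 over 247 at Day 4. A wrong label of the embryo library labelled wild type would not lower these RNAs in the Day 4 pair. That pair, 1 library against 1, had a median of -3.16 over 8 domain genes (95% interval from resampling genes -3.81 to -2.33). Some of these genes overlap in position, so the interval measures no spread between libraries. The low Day 4 values were also part of the pattern itself. A wrong embryo label does not account for them, and whether that label is right stays open. The 14 genes within 1 Mb outside had medians of -0.0656 in the embryos and 0.06 at Day 4. Dlk1, expressed from the other parental copy, stood at 4.20 FPKM against 8.62 and 7.20. Rtl1, also protein-coding, went the other way, with 3.97 FPKM against 0.377 and 0.478, and 2.73 against 0.0280 at Day 4. Antisense transcripts over Rtl1 cannot be separated, so its own level is uncertain. Dlk1 was not lower in the T_Y88A embryo libraries, so silencing of every gene of the domain is not what the values show. A candidate explanation is silencing of the domain's maternally expressed RNAs, such as Rian and Meg3, in the cells that gave the T_Y88A libraries. Whether the T_Y88A genotype or the history of the cells set it stays open, as no label names a second T_Y88A line.

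Blood and endothelial genes were low in both T_Y88A embryo libraries, and a candidate explanation is fewer erythroid cells in the sort. Erythroid RNA was abundant in the library labelled wild type despite the gate for T (Hba-x at 1625 FPKM). All 13 erythroid markers, a list written for this test, were lower, by medians of 6.29-fold at TS12 and 3.34-fold at TS13; the most abundant in the library labelled wild type were Hbb-bh1, Hba-a2 and Hba-x. A loss of cells alone lowers them by a common factor, and the SD of their log2 ratios was 0.64 and 0.56. Such a spread cannot be told apart from lower expression per cell. Hba-a1 (184 FPKM, then 0.0115 and 0.0232) was not in this list and fell more than its members. The SD therefore depends on leaving Hba-a1 out, whose reads may be shared with Hba-a2. Endothelial genes were low as well, with a median of -0.95 over 9 markers (95% interval over genes -1.52 to -0.77), 6 of them called. Etv2 (-0.53) and Sox17 (-0.42) of the blood and endothelium list were not among these markers. Fewer erythroid cells would not by itself lower endothelial genes. However, Cdh5 and other markers belong to the list whose fall raised the question, so their median restates the pattern and is no separate test. The T_Y88A genotype stays open for both.

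Presomitic genes were low in both T_Y88A embryo libraries. The stage difference alone would put the library that pools both stages between the T_Y88A libraries. This assumes that the pool held only the labelled stages and varied like the T_Y88A libraries, which 1 library cannot show. Under that assumption, 9 of all 15 genes of the list argue against stage alone, being at least 2-fold lower in both. The count of these genes restates the pattern and is no separate test. This count was taken up after a first comparison gave slightly overlapping intervals over genes. That comparison set the TS13 minus TS12 median of -0.28 (95% interval -0.50 to 0.04) against the list median of -1.30 (-1.94 to -0.47). For Wnt5a and Wnt5b, which lie between, stage stays open. Fewer presomitic cells in the sort and lower expression per cell under the T_Y88A genotype were not told apart and stay open.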

How the results depend on the processing

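Leaving out genes listed at 0 was chosen after seeing the data; the other alternatives were set before. The limma count of 256 genes in embryos became 0 with no filter and 17 under quantile normalization; the other settings gave 188 to 313. Its share of higher calls, 32.0%, was 42.6% at a mean of at least 5 FPKM, 21.3% without the variance trend and 17.6% under quantile normalization. Leaving out a T_Y88A embryo library leaves this fit no residual degrees of freedom, so it has no value. The 201 genes past 2-fold in both T_Y88A libraries, the 114 between stages and the 227 at Day 4 became 409, 286 and 441 with a pseudocount of 0.1, 43, 27 and 80 with a pseudocount of 5, 75, 50 and 133 at a mean of at least 5 FPKM, 750, 596 and 1218 at 1.5-fold and 23, 8 and 27 at 4-fold, as looser and stricter limits must. With 1 T_Y88A embryo library left out, the 201 became 360 to 395, since 1 library then decides. The 10 genes called over embryo and Day 4 libraries became 6 with a pseudocount of 0.1, 1 with no filter, 1 at a mean of at least 5 FPKM and 6 with genes listed at 0 left out, and 4 to 24 with 1 library left out. In that fit, leaving out any library other than a T_Y88A embryo library leaves 1 system to set the genotype effect. The 10 called lists became 0 with an estimated correlation and 0 with fry. Where not given, the cause was not tested.

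Of the values of named genes and called lists under the alternatives, 335 for embryo genes stayed the same and 45 lost the call but kept the direction; for lists these were 92 and 26, and for genes of the 5-library fit 80 and 39. The same means direction and side of the threshold, except for embryo genes and lists with a T_Y88A embryo library left out, where no test exists and only the direction was compared (29 and 27 of the 335, 10 and 10 of the 92). At Day 4, 151 stayed past 2-fold and 1 did not. Camera's direction for BMP targets was opposite with no filter (median 0.0238). With T_Y88A TS12 or T_Y88A TS13 left out, the log2 difference ran from -1.26 to 0.0812 for T, from -2.11 to 0.16 for Wnt3a, from -0.36 to 0.33 for Evx1 and from -0.0290 to 0.45 for Cdx2, none of them called. No paired analysis was possible because the labels give no replicate numbers. Depth is known only as a ratio, and Day 4 T_Y88A, the shallowest library, is the least precise for low genes.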

Other observations

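Among other imprinted or methylation-sensitive genes, chosen after their values were seen, Peg13 and Rhox5 fell in the T_Y88A embryo libraries. The others given here did not pass, the group was not tested as a list, and methylation was not measured. Peg13, an imprinted noncoding RNA, fell from 4.30 FPKM in the library labelled wild type to 0.108 and 0.0419 in T_Y88A, but stood at 0.658 and 0.619 in the Day 4 libraries. Rhox5, an X-linked homeobox gene active in extraembryonic tissue, fell from 4.96 to 0.239 and 0.371 FPKM, and at Day 4 stood at 5.25 and 8.47. Igf2, which neighbours H19 and is expressed from the other parental copy, stood at 170 FPKM in the embryo library labelled wild type and at 207 and 304 in T_Y88A (adjusted p = 0.202). The log2 differences of further imprinted genes in the embryos did not pass either: Snrpn (0.72; 29.4 FPKM, then 63.2 and 37.9), Dlk1 (0.77), Kcnq1ot1 (0.34), Cdkn1c (0.18), Grb10 (0.01), Peg3 (-0.05), Mest (-0.08) and Igf2r (-0.14).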
